A study of Homo sapiens with 42 samples.

How the data were processed

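Messenger RNA was measured on Affymetrix U133 Plus 2 arrays, 1 array per RNA sample, in the human multiple myeloma line RPMI-8226 carrying an inducible shRNA against BMI1 or an inducible control shRNA. Biotin-labelled cRNA was hybridized, and replicates were not pooled. The deposited values have the unit intensity: linear MAS5 signals per probe set, which the authors' processing notes name without a version. The mean signal after trimming 2% at each end was 150.02 to 150.03 on every array, so each array had been scaled to a common target. Arrays have no read depth, and their number, 3 per group, limits the precision.

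The table held 54675 probe sets, of which 62 array controls were left out. A probe set was retained where at least 3 of the 42 arrays read at or above the array's own median, which left 35235. Values were transformed as log2(value + 5.4), where 5.4 is the 25th percentile of all values. Of the 54675 probe sets, 41097 were annotated to a single gene symbol, 1801 to several and 11721 to none. Each gene was represented by its brightest retained probe set among the 28475 retained ones with a single symbol, giving 14705 genes. A total of 7362 genes had several retained probe sets. BMI1 was read separately, because its probe set is annotated to BMI1 and to the readthrough transcript COMMD3-BMI1.

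Arrays were grouped by line, doxycycline and time as the labels give them, in 14 groups of 3. The 0 h arrays of the BMI1-shRNA line carry conflicting labels: the title gives no doxycycline, the characteristics give doxycycline, and the source name gives the control line. Of the 15 comparisons they entered only that of 48 h with 0 h in that line, beside the shared estimate of variance. They also entered the line difference at 0 h, the test of hairpin expression without doxycycline built on it, and the difference of the lines' time effects. A linear model with 14 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend). It had 28 residual degrees of freedom and 8.64 prior degrees of freedom. The limma tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 14705 genes.

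There were 15 comparisons. Doxycycline was set against no doxycycline within each line at 24, 32 and 48 h and as the mean of the 3 times. The doxycycline effect in the control-shRNA line was subtracted from that in the BMI1-shRNA line, again at each time and as the mean. The lines were compared without doxycycline over the mean of the 3 times, and 48 h was compared with 0 h without doxycycline in each line. A total of 29 gene lists holding 672 symbols, 527 of them tested, covered Polycomb complexes, HOX and other developmental genes, cell cycle, apoptosis, plasma cell identity, stress, metabolism, interferon and markers of other cell types. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 29 lists within a comparison, and again with an estimated correlation.

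The groups, comparisons, filters, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. BMI1 is named first. For comparisons averaged over times, the 10 highest and 10 lowest log2 fold changes among called genes with the same sign at each of the 3 times are named. For the comparisons of 48 h with 0 h, the genes named are those whose groups do not overlap, and for doxycycline at single times the 3 highest and 3 lowest called genes. If fewer than 5 passed, the 5 smallest p would be named. From each list, up to 4 members with the largest absolute log2 fold change are eligible. BCL2L11, PMAIP1, BBC3, BCL2, MCL1, CDKN2A, CDKN2B, CDKN1A, CCND2, MYC, IRF4, HOXA9, HOXC13, RING1, RNF2, PCGF2 and EZH2 were always to be given. BBC3, HOXA9, HOXC13 and RNF2 had no retained probe set with a single symbol and were not tested.

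The model was tested on simulated data with 100 changed genes of each size and noise drawn independently for each gene and array. On the real arrays part of the spread is shared between genes, so false calls there can be more frequent. For the doxycycline effect in the BMI1-shRNA line over 3 times it recovered 65% of changes of log2 0.5 and 89% of log2 1, with 5 false calls. For the difference between lines at 24 h it recovered 27% and 61%. Alternatives tried were pseudocounts of 1 and of the median value, quantile normalization, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, all probe sets as features, no intensity trend, fitting only the groups of the comparison, the replicate number as a block, and leaving out each array in turn. Replicate numbers were not used to pair arrays: deviations from the group means correlated at a mean r across genes of 0.002 between arrays with the same number and -0.001 between arrays with different numbers. Fits without the 0 h arrays, means of 24 and 32 h, list tests after quantile normalization, the line difference at 0 h and tests of differences between times and between the lines' time effects were added after seeing the data.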

Results

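RPMI-8226 is an established cell line from multiple myeloma, a cancer of plasma cells. Cells carried an shRNA against BMI1, a subunit of the gene-silencing Polycomb repressive complex PRC1, or a control shRNA, and 100 ng/ml doxycycline switched the hairpin on. Each line was profiled with and without doxycycline at 24, 32 and 48 h and without it at 0 h, in 14 groups of 3 arrays (21 arrays per line). The median probe set signal ranged from 16 to 22.5 over the arrays. Across genes, correlations between arrays of a group ran from 0.979 to 0.985 and those between lines from 0.958 to 0.967. The first principal component held 35.0% of the variance and separated the lines. The ratio of the GAPDH 3-prime to 5-prime probe sets, a sign of RNA quality, was 1.03 ± 0.0401 (SD, n = 21) in the control-shRNA line and 0.935 ± 0.0251 (SD, n = 21) in the BMI1-shRNA line. The labels number the replicates without saying whether they are separate cultures, so p-values measure only the spread between arrays. Errors of log2 fold changes are standard errors from limma, and errors of signals are SDs.

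The comparison of doxycycline with no doxycycline in the BMI1-shRNA line asked what changed when the BMI1 hairpin was induced. BMI1 itself fell 5.4-fold on the mean of the 3 times, a log2 fold change of -2.43 ± 0.06 (limma adjusted p = 1.05e-28; lower at 3 of 3 times, 9 arrays a side). Its probe set read 206.9 ± 34.1, 166.6 ± 17.3 and 158.9 ± 25.6 at 24, 32 and 48 h with doxycycline, against 926.9 ± 154, 976.9 ± 62.5 and 1021 ± 125 without it (n = 3 each). The highest dosed array read 234 and the lowest undosed array of that line 758.3. In the control-shRNA line the same probe set read 1332 ± 32.8, 1192 ± 12.9 and 1206 ± 22.7 with doxycycline, and its log2 fold change was 0.03 ± 0.06 (limma adjusted p = 0.987).

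**Figure D1:**
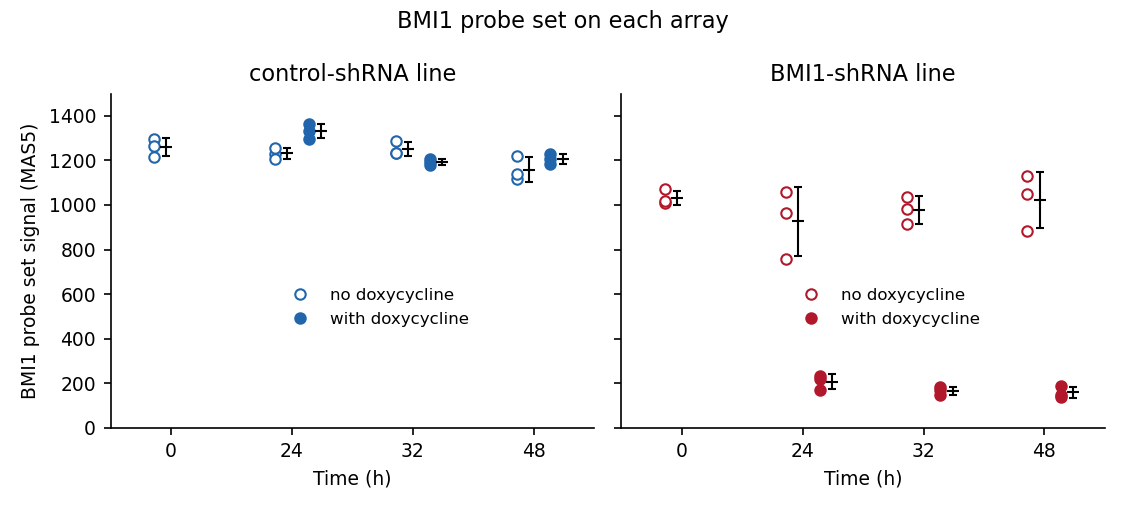
Signal of the BMI1 probe set on each array (points) with the mean and SD of 3 arrays per group, by time and doxycycline, in the BMI1-shRNA and control-shRNA lines. The 9 dosed arrays of the BMI1-shRNA line sit between 139.8 and 234, below every other array.

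Beyond BMI1, the 10 genes that fell furthest on induction included enzymes, transporters and a kinase. IDH1, the cytosolic isocitrate dehydrogenase, fell 5.42-fold (-2.44 ± 0.06, limma adjusted p = 1.75e-27), from a signal of 819.8 ± 109 to 147.5 ± 24.6 (n = 9 each). SFXN1, a mitochondrial serine transporter, changed by -1.98 ± 0.04 and EVI5, a TBC-domain protein, by -1.96 ± 0.12. Adenosine deaminase, ADA, changed by -1.23 ± 0.04, the atypical kinase MAPK6 by -1.20 ± 0.03, and API5, an inhibitor of apoptosis, by -1.18 ± 0.04. The zinc importer SLC39A10 (-1.17 ± 0.04), the mitochondrial ribosomal protein MRPL10 (-1.11 ± 0.05) and the p53-induced TP53INP1 (-1.08 ± 0.09) also fell. SLITRK5, a neuronal membrane protein, fell by 1.55 ± 0.09 on the log2 scale, and it fell in the control-shRNA line as well. Each of these 10 genes was lower at 3 of 3 times.

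The genes with the largest rises were dim. VIPR2, a receptor for vasoactive intestinal peptide, rose by 1.16 ± 0.28, and the cytokine IL11 rose by 1.00 ± 0.30, from 11.9 ± 11.4 to 28.1 ± 15.3. CCDC157 (0.98 ± 0.29), SBSN (0.90 ± 0.28), RND1 (0.88 ± 0.22), LRRC17 (0.86 ± 0.26), HAVCR1P1 (0.82 ± 0.25), GAS5-AS1 (0.82 ± 0.25), ERN2 (0.81 ± 0.24) and the interferon-induced IFIT1 (0.81 ± 0.17) followed. Of these 10 genes, 7 lost the call when 1 of the arrays was left out and 9 in another setting, VIPR2 and RND1 in settings only. The 10 largest falls lost it in none of these. IFIT1 kept its call throughout, at a signal of 75.2 ± 7.21 against 43.9 ± 14.4.

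Among regulators of survival, BCL2L11, the pro-apoptotic protein BIM, rose by 0.39 ± 0.04 (limma adjusted p = 2.1e-08), from 756.1 ± 38.1 to 997.9 ± 96.1 (n = 9 each, higher at 3 of 3 times). The myeloma factor IRF4 rose by 0.15 ± 0.03 (adjusted p = 0.00127) and RING1, a ubiquitin ligase of PRC1, by 0.11 ± 0.03 (adjusted p = 0.0286), both at 3 of 3 times in limma. IRF4 had a similar value in the control-shRNA line, where it did not pass, and its difference between the lines did not pass. IRF4 lost the call when 24 and 32 h alone were averaged, a setting chosen after seeing the data. RING1 lost it in other settings and when single arrays were left out. CDKN2A, the textbook target of BMI1 repression, had a log2 fold change of 0.01 ± 0.04 (adjusted p = 0.955) at a signal of 2995.3 ± 174 against 2979.6 ± 172. Other values that did not pass in limma were 0.10 ± 0.05 for PMAIP1, -0.05 ± 0.06 for BCL2, 0.00 ± 0.03 for MCL1, -0.21 ± 0.12 for CDKN2B and -0.13 ± 0.10 for CDKN1A. CCND2 had 0.14 ± 0.04 (adjusted p = 0.0509), MYC -0.03 ± 0.06, PCGF2 0.01 ± 0.07 and EZH2 0.07 ± 0.03.

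In total 1220 of 14705 genes changed over the mean of 3 times, 578 up and 642 down, with a median absolute log2 fold change of 0.23. Only 15 changed at least 2-fold, 2 up and 13 down. At 24 h, 237 genes changed (78 up, 159 down), at 32 h 322 (77 up, 245 down) and at 48 h 789 (217 up, 572 down). Of the 237 called at 24 h, 223 (94.1%) had the same direction at 48 h. At 24 h the highest were LINC00598 at 1.65, RND1 at 1.46 and TMEM147-AS1 at 1.12, and the lowest were IDH1, SYT5 at -1.65 and EVI5. At 32 h VIPR2 was at 1.96, CCDC157 at 1.88 and IL11 at 1.83, and IDH1, EVI5 and SFXN1 were the lowest. At 48 h IL34, a cytokine for macrophages, was at 1.65, and ZMAT4 and SOX2, a transcription factor of neural and stem cells, were both at 1.27. The 24 h count was 138 without dosed replicate 1 or dosed replicate 2 of that time, and 148, 152 and 155 without undosed replicates 1, 2 and 3. The 32 h count was 214 without undosed replicate 3 of that time.

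**Figure D2:**
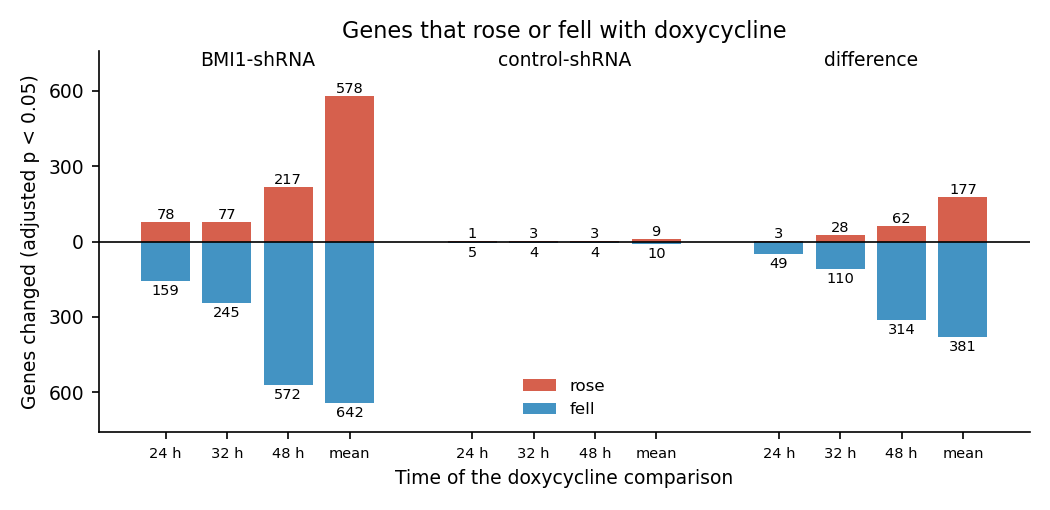
Bars count the genes that rose or fell with doxycycline (adjusted p under 0.05, 14705 genes tested) in each line and in the difference between lines, at 24, 32 and 48 h and for their mean. The BMI1-shRNA line had 1220 genes for the mean and the control-shRNA line 19.

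None of the 29 gene lists was called in this comparison, where the lowest adjusted p was 0.141, and none with an estimated correlation. By limma 56 genes of 22 lists changed. Of 47 list members called and eligible for naming, 19 lost the call in at least 1 other setting and 7 without some single array (BCL2L2, DDIT4, ISG20, MCOLN1, MRPL24, NDUFB10 and SUZ12). In the PRC1 list 2 of 15 measured genes rose, RING1 and CBX6 (0.21 ± 0.05), and PCGF3 fell (-0.51 ± 0.10), with 4 and 1 adjusted over the list alone. In the PRC2 list of 11, JARID2 rose (0.22 ± 0.04) and RBBP4 (-0.14 ± 0.03) and SUZ12 (-0.13 ± 0.04) fell, 2 and 2 adjusted over the list alone. As the mean of its probe sets SUZ12 had the opposite sign, 0.20. None of the 17 HOX genes measured, of 39 in the list, passed at either level. Some of the 17, such as HOXB1 and HOXC6, read near background. Of 25 other developmental regulators repressed by Polycomb, 2 rose, SOX2 (0.80 ± 0.10) among them, as many as adjusted over the list alone. CDKN1B rose (0.16 ± 0.03) and CDKN3 fell (-0.24 ± 0.03) among 7 CDK inhibitors, 1 and 1 adjusted over the list alone.

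Genes of DNA replication and mitosis that passed were lower. E2F1 (-0.45 ± 0.12), the replication clamp PCNA (-0.39 ± 0.04) and DSCC1 (-0.21 ± 0.04) were among 4 of 37 in the G1/S list that fell. KIF4A (-0.46 ± 0.04), the mitotic kinase AURKA (-0.37 ± 0.04) and KIF2C (-0.24 ± 0.03) were the 3 of 36 in the G2/M list that fell, and none rose in either list. The numbers adjusted over the list alone were 4 and 3. Of 25 p53 targets 3 fell, TP53INP1, the death receptor FAS (-0.58 ± 0.06) and RRM2B (-0.31 ± 0.05), with 1 up and 3 down adjusted over the list alone. Of 25 MYC targets NOLC1 fell (-0.18 ± 0.04), alone at both levels, and none of 28 cytosolic ribosomal proteins passed at either.

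Among stress and metabolic lists, PDIA4, a chaperone of the endoplasmic reticulum, fell (-0.83 ± 0.05) with EDEM1 (-0.24 ± 0.04) while DNAJB9 (0.21 ± 0.03) and the stress sensor ERN1 (0.16 ± 0.04) rose, out of 23 genes of the unfolded protein response (2 up and 4 down adjusted over the list alone). The cystine transporter SLC7A11 (-0.91 ± 0.08), the folate enzyme MTHFD2 (-0.59 ± 0.05) and SLC7A1 (-0.36 ± 0.03) were among 5 of 29 ATF4 genes that fell, as many as adjusted over the list alone. ATP5PB (-0.44 ± 0.05) and NDUFB10 (-0.14 ± 0.04) fell out of 37 genes of oxidative phosphorylation, the same number adjusted over the list alone. MRPL37 (-0.20 ± 0.04), GFM1 (-0.20 ± 0.04) and MRPS30 (-0.19 ± 0.04) fell and MRPL24 (0.18 ± 0.06) rose out of 29 genes of the mitochondrial ribosome, also 3 and 1 adjusted over the list alone. In cholesterol synthesis lanosterol synthase, LSS, fell (-0.52 ± 0.04) and INSIG1 rose (0.21 ± 0.04) out of 18, as adjusted over the list alone. DDIT4 fell (-0.20 ± 0.06) out of 32 genes of glycolysis and hypoxia, where 0 passed adjusted over the list alone.

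Of 18 plasma cell genes 5 rose, CD38 (0.24 ± 0.05) and IRF4 among them, and 6 adjusted over the list alone. The pro-apoptotic list of 11 held the rise of BCL2L11 and a fall of BNIP3L (-0.35 ± 0.04), 1 and 2 adjusted over the list alone. BCL2L2 rose (0.29 ± 0.09) among 6 anti-apoptotic genes. Of 26 interferon-stimulated genes IFIT1 rose and ISG20 fell (-0.23 ± 0.07). ICAM1 (-0.36 ± 0.04) and LTB (-0.28 ± 0.08) fell among 19 NF-kB targets. KLF4 rose (0.51 ± 0.12) and 2 genes, JUN (-0.37 ± 0.06) among them, fell of 20 immediate early genes, where 1 and 3 passed adjusted over the list alone. UVRAG (-0.53 ± 0.04) and MCOLN1 (-0.28 ± 0.09) fell of 23 lysosome and autophagy genes, and none of 10 replication-dependent histones passed. The numbers up and down adjusted over the list alone were 1 and 0 for anti-apoptotic genes, 1 and 1 for interferon, 0 and 2 for NF-kB, 1 and 2 for lysosome, 0 and 0 for histones and 0 and 1 for epithelial genes. Of markers of other cell types KRT18 alone fell (-0.19 ± 0.04) among 4 epithelial genes, with no call among 2 T cell, 3 monocyte, 1 erythroid and 3 fibroblast genes. Median, mean and test differed in sign for HOX genes, p53 targets, ATF4 genes, glycolysis, interferon, immediate early genes, histones, lysosome and monocyte markers.

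The control-shRNA line asked what doxycycline and a control hairpin did. SLITRK5 fell 2.39-fold (-1.26 ± 0.09, limma adjusted p = 9.25e-12, lower at 3 of 3 times), from 152.6 ± 8.91 to 60.9 ± 5.91 (n = 9 each). SLC18B1, a vesicular polyamine transporter, changed by -0.79 ± 0.05, the spliceosome-associated CWC27 by -0.48 ± 0.04 and IMP3, a small nucleolar ribonucleoprotein, by -0.36 ± 0.05. ING3 (-0.35 ± 0.05), IRF2 (-0.34 ± 0.05), CHPT1 (-0.30 ± 0.03), the metallothionein MT2A (-0.23 ± 0.04), BCAT1 (-0.19 ± 0.03) and SLC17A5 (-0.16 ± 0.03) made up the 10 falls. The 9 rises were B3GNT3 (1.02 ± 0.17, at a signal of 19.6 ± 6.27), TMT1A (0.30 ± 0.04), SAMD9L (0.30 ± 0.04), LPGAT1 (0.28 ± 0.04), GIRGL (0.25 ± 0.04), the caveolins CAV2 (0.25 ± 0.05) and CAV1 (0.21 ± 0.03), the mTOR inhibitor DEPTOR (0.16 ± 0.03) and the plasma cell factor PRDM1 (0.14 ± 0.03). PRDM1 had the opposite sign, -0.02, as the mean of its probe sets.

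These 19 genes stood against 882 at an unadjusted p under 0.05 in limma. At 24 h 6 genes changed, MATK (1.92 ± 0.35) the only rise, and the count was 3 without dosed replicate 1 or 2 of that time. At 32 h 7 changed, XYLB (1.05 ± 0.22) the highest. Without undosed replicate 1, 2 or 3 of 32 h the count was 4, 4 or 2, and without dosed replicate 2 or 3 it was 2 or 4. At 48 h 7 changed, with SLC44A1 (0.29 ± 0.06) among 3 rises, and the count was 4 without undosed replicate 3 of 48 h. SLITRK5, SLC18B1 and CWC27 were the 3 lowest at each time. Over the mean of the times, CAV2, DEPTOR, MT2A and SLC17A5 lost the call without some single array and in another setting, and CAV1, PRDM1, TMT1A, BCAT1 and ING3 in another setting only. None of the genes always given passed: BCL2L11 had 0.07 ± 0.04, PMAIP1 -0.06 ± 0.05, BCL2 0.01 ± 0.06, MCL1 0.01 ± 0.03, CDKN2A 0.02 ± 0.04, CDKN2B -0.37 ± 0.12 and CDKN1A -0.21 ± 0.10. CCND2 had -0.04 ± 0.04, MYC 0.02 ± 0.06, IRF4 0.12 ± 0.03, RING1 -0.05 ± 0.03, PCGF2 -0.02 ± 0.07 and EZH2 0.01 ± 0.03. No list was called, the lowest adjusted p being 0.054 for plasma cell genes, where PRDM1 alone of 18 rose and 5 rose adjusted over the list alone. With the replicate block in the list test the plasma cell list was called, but not with an estimated correlation, and its adjusted p ran from 0.0449 to 0.0952 over the alternatives.

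The difference of the doxycycline effects between the lines asked what the BMI1 hairpin did beyond doxycycline and a control hairpin. Each hairpin was carried by a single line, so this difference also holds any difference in how the lines respond to doxycycline. BMI1 differed by -2.47 ± 0.08 (limma adjusted p = 1.46e-23, lower at 3 of 3 times, 18 arrays a side), with -2.25, -2.45 and -2.71 at 24, 32 and 48 h (± 0.14 each). IDH1 differed by -2.62 ± 0.09 (adjusted p = 2.9e-23 in limma), SFXN1 by -2.08 ± 0.06 and EVI5 by -1.81 ± 0.16. ADA (-1.26 ± 0.06), API5 (-1.19 ± 0.06), MAPK6 (-1.18 ± 0.05) and SLC39A10 (-1.17 ± 0.06) followed, each at 3 of 3 times. BCL2L11 rose more in the BMI1-shRNA line, by 0.32 ± 0.06 (limma adjusted p = 0.000917, 3 of 3 times), and it did not pass when 24 and 32 h alone were averaged. RING1 passed narrowly at 0.16 ± 0.05 and lost the call in other settings and when single arrays were left out.

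Dim genes completed the 10 lowest: ST6GALNAC6 (-1.42 ± 0.41), LOC100507351 (-1.17 ± 0.32) and LGR6 (-1.16 ± 0.34), all of which lost the call without some single array. The 10 highest were LRRC17 (1.39 ± 0.37), CCDC157 (1.38 ± 0.41), ZNF771 (1.34 ± 0.39), LINC00598 (1.23 ± 0.36), SPINT1-AS1 (1.17 ± 0.31), PSG4 (1.12 ± 0.33), ANKRD36B (0.97 ± 0.28), the histone demethylase KDM4D (0.90 ± 0.22), D2HGDH (0.82 ± 0.22) and SOX2 (0.72 ± 0.14). All 10 lost the call in at least 1 other setting and 5 without some single array. SOX2 had the brightest signal of these, 100.2 ± 49 against 89.6 ± 62.4 over both sides of the contrast (n = 18 each). Each side pools arrays of both lines. Without doxycycline SOX2 read 29.9 ± 3.36 in the BMI1-shRNA line, where it rose, and 142.6 ± 27.6 in the control-shRNA line (n = 9 each). It was therefore dim before its rise.

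The difference passed for 558 genes, 177 up and 381 down, 21 of them at least 2-fold. Of the 1220 genes called in the BMI1-shRNA line, 510 also passed the difference in the same direction. At 24 h 52 genes passed (3 up, 49 down), at 32 h 138 (28 up, 110 down) and at 48 h 376 (62 up, 314 down). Of the 49 falls at 24 h, 47 were also falls at 48 h, where 1.05 would be shared by independent sets. The calls at both times share one estimate of each gene's variance, so these sets are not fully independent. The single-time rises were LINC00598 (2.68 ± 0.63), the Polycomb-like SCML1 (0.64 ± 0.14) and NETO2 (0.30 ± 0.07) at 24 h, and ADAD2-AS1 (3.00 ± 0.74), CCDC157 and TSPAN18 (2.79 ± 0.59) at 32 h. At 48 h they were KIR3DL1 (2.33 ± 0.64), LRP5L (1.80 ± 0.51) and SOX2 (1.27 ± 0.25). The lowest beside IDH1, SFXN1 and EVI5 were CGREF1 (-2.36 ± 0.55) and H3-4 (-2.31 ± 0.59) at 32 h and MED12L (-2.08 ± 0.57) at 48 h, all dim. Averaging 24 and 32 h alone, an alternative chosen after seeing the data, gave 207 genes.

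**Figure D3:**
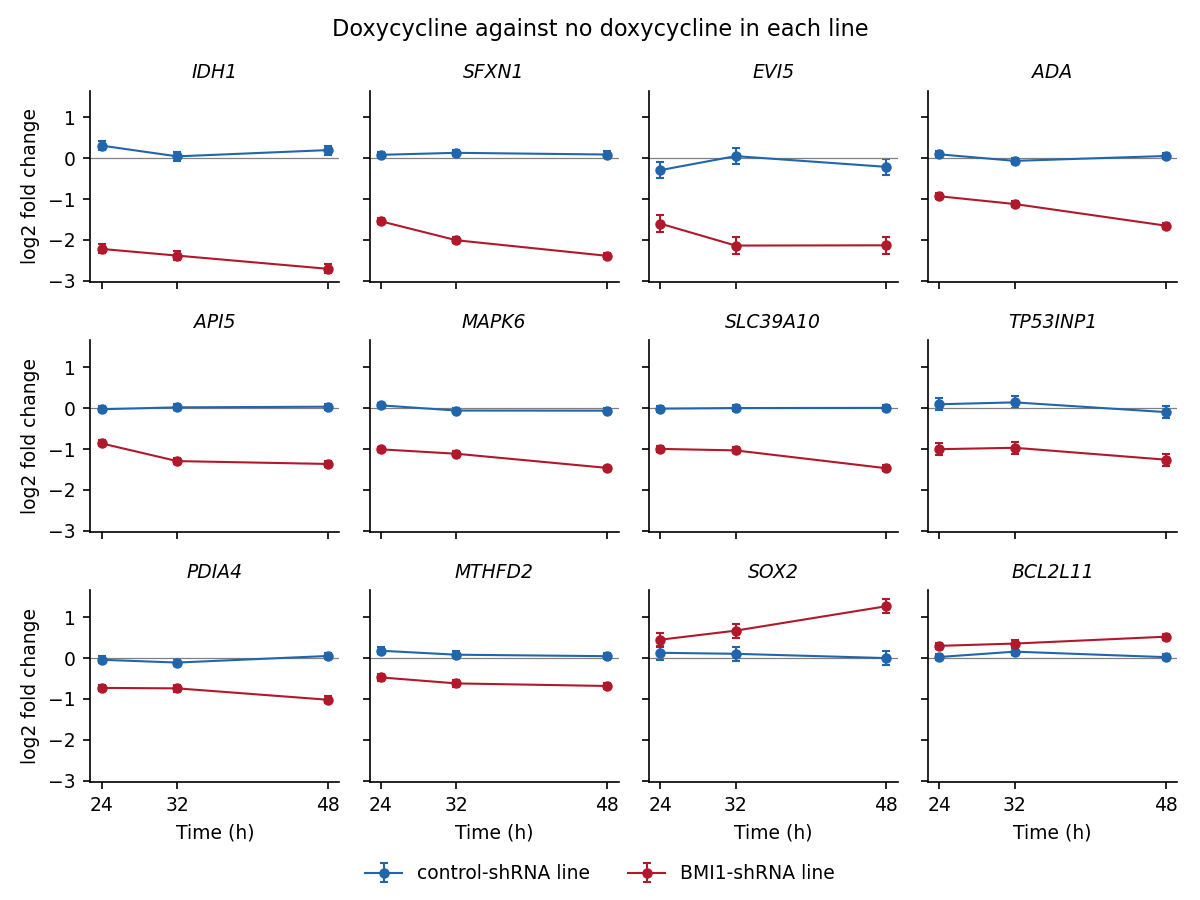
Log2 fold change with doxycycline (± SE) at 24, 32 and 48 h for 12 named genes in the BMI1-shRNA and control-shRNA lines, n = 3 arrays a side at each point. IDH1 falls from -2.22 at 24 h to -2.71 at 48 h in the BMI1-shRNA line, and BCL2L11 stands at 0.30, 0.36 and 0.52.

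Over the mean of the times no list was called (lowest adjusted p 0.0679, ATF4 genes). In limma 34 genes of 17 lists passed. Of 29 called list members eligible for naming, 16 lost the call in at least 1 other setting: BCL2L11, CD38, CDKN3, DNAJB9, DSCC1, EDEM1, GFM1, INSIG1, JARID2, JUN, MRPS30, RBBP4, RRM2B, SOX2, SUZ12 and TP53INP1. CD38, MRPS30, RBBP4 and SUZ12 also lost it without some single array. JARID2 (0.36 ± 0.06) was higher and SUZ12 (-0.17 ± 0.05) and RBBP4 (-0.16 ± 0.05) lower of 11 PRC2 genes, and SUZ12 changed sign, to 0.34, as the mean of its probe sets. TP53INP1 (-1.13 ± 0.12), FAS (-0.62 ± 0.09) and RRM2B (-0.36 ± 0.07) were lower of 25 p53 targets. PCNA (-0.40 ± 0.06), DSCC1 (-0.32 ± 0.06), KIF4A (-0.47 ± 0.06), AURKA (-0.36 ± 0.05) and CDKN3 (-0.18 ± 0.05) were lower among cell cycle genes. PDIA4 (-0.80 ± 0.07), EDEM1 (-0.26 ± 0.05), SLC7A11 (-0.78 ± 0.11), MTHFD2 (-0.69 ± 0.07), LSS (-0.60 ± 0.06), ATP5PB (-0.52 ± 0.07), GFM1 (-0.27 ± 0.06), MRPL37 (-0.26 ± 0.06) and MRPS30 (-0.20 ± 0.06) were lower among metabolic and stress genes. DNAJB9 (0.26 ± 0.05), CD38 (0.26 ± 0.07) and INSIG1 (0.20 ± 0.05) were higher. BNIP3L (-0.40 ± 0.05), UVRAG (-0.49 ± 0.06), JUN (-0.37 ± 0.09) and ICAM1 (-0.26 ± 0.05) were lower.

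Values of the remaining fixed genes did not pass: PMAIP1 0.16 ± 0.07, BCL2 -0.06 ± 0.09, MCL1 -0.01 ± 0.05, CDKN2A -0.01 ± 0.06, CDKN2B 0.16 ± 0.18, CDKN1A 0.09 ± 0.14, CCND2 0.18 ± 0.06, MYC -0.04 ± 0.08, IRF4 0.03 ± 0.05, PCGF2 0.03 ± 0.10 and EZH2 0.06 ± 0.04. Adjusted over the list alone, the numbers up and down were 1 and 2 for PRC2, 0 and 3 for p53 targets, 0 and 2 for G1/S, 2 and 4 for G2/M, 0 and 5 for ATF4 genes, 1 and 2 for the unfolded protein response and 1 and 1 for cholesterol synthesis. They were 1 and 0 for PRC1 and for other developmental regulators, 0 and 1 for CDK inhibitors, oxidative phosphorylation and NF-kB, 0 and 3 for the mitochondrial ribosome, 2 and 0 for plasma cell genes and 1 and 1 for the pro-apoptotic list. Median, mean and test differed in sign for HOX genes, other developmental regulators, CDK inhibitors, p53 targets, plasma cell genes, glycolysis, NF-kB targets, epithelial and fibroblast markers.

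At single times the preset test called 4 lists at 24 h, 4 at 32 h and 1 at 48 h, and the ribosomal list was called in both directions. At 24 h the 28 cytosolic ribosomal proteins were lower, by a mean of -0.19 that became 0.01 after quantile normalization (0 of 28 higher, adjusted p = 4.08e-06; adjusted p = 0.671 with an estimated correlation), as were 37 genes of oxidative phosphorylation (mean -0.10 and 0.00 after quantile normalization, adjusted p = 0.000116; adjusted p = 0.633 with an estimated correlation). Genes of the unfolded protein response (mean -0.11, adjusted p = 0.0127; 0.191 as the adjusted p with an estimated correlation) and ATF4 genes (mean -0.04, adjusted p = 0.015; 0.0573 as the adjusted p with an estimated correlation) were lower too, with 1 of 23 and 2 of 29 genes passing on their own. At 32 h the same 4 lists were lower, with adjusted p = 0.00479, 0.00479, 0.0392 and 0.0159 in that order, and adjusted p = 0.91, 0.91, 0.44 and 0.0473 with an estimated correlation. At 48 h the ribosomal list was higher (mean 0.19 and 0.01 after quantile normalization, 28 of 28 higher, adjusted p = 0.00109; adjusted p = 0.978 with an estimated correlation). No ribosomal gene passed on its own at any of these times. After quantile normalization, tried after seeing the data, none of these lists was called, and the ribosomal mean at 32 h was -0.01. The percent of all signal in the 100 brightest probe sets, which include 11 of the 28 ribosomal ones, was 8.42 with and 9.04 without doxycycline at 24 h in the BMI1-shRNA line and 8.28 and 8.07 in the control-shRNA line. At 48 h it was 9.2 and 9.09 in the BMI1-shRNA line and 8.54 and 9.36 in the control-shRNA line.

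The lines themselves were compared without doxycycline, over the mean of 24, 32 and 48 h. BMI1 was lower in the BMI1-shRNA line, at 80% of the control-shRNA level (-0.32 ± 0.06, limma adjusted p = 1.36e-05, lower at 3 of 3 times, 9 arrays a side). FHOD3, an actin regulator, was higher (4.81 ± 0.17, 393.5 ± 28.3 against 9.3 ± 3.77), and UBE2QL1, a ubiquitin-conjugating enzyme, was lower (-5.03 ± 0.12, 5.4 ± 3.14 against 335.0 ± 18). The weaker side of both is near background, and the size of both differences depended on the pseudocount: larger with 1 and smaller with the median value. Other genes higher in the BMI1-shRNA line were OLFM4 (4.36), BEND4 (4.10), FAR2 (4.05), LINC00588 (4.04), the transcription factor BHLHE41 (4.02), CPXM1 (3.98), the cadherin CDH3 (3.91), the laminin chain LAMB3 (3.86) and SCEL (3.71). Lower ones were CDHR1 (-4.87), B3GAT2 (-4.76), ARMCX3 (-4.34), the small heat shock protein HSPB8 (-4.22), CT83 (-4.13), the gap junction protein GJA1 (-3.84), the cytokine receptor chain IL2RG (-3.76), MAP4K4 (-3.71) and TCEAL8 (-3.71). OLFM4, BEND4, FAR2, LINC00588, SCEL, CDHR1, B3GAT2, ARMCX3, HSPB8, CT83, IL2RG, MAP4K4 and TCEAL8 also had a weaker side below the median value of 18.8. The size of their differences depends on the pseudocount too. All 20 genes kept their calls in every setting and with every array left out.

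In all, 6443 genes (43.8%) differed, 3203 higher and 3240 lower, 663 of them at least 2-fold. Apoptosis and cell cycle regulators were among them: BCL2A1 (-2.99 ± 0.18) and MCL1 (-0.43 ± 0.03) were lower, and BCL2 (0.76 ± 0.06), BCL2L1 (0.72 ± 0.08), BCL2L11 (0.45 ± 0.04) and PMAIP1 (0.43 ± 0.05) higher. CDKN2B (1.37 ± 0.12), CCND2 (1.12 ± 0.04), CDKN1B (0.50 ± 0.03), CDKN2A (0.40 ± 0.04), MYC (0.27 ± 0.06) and IRF4 (0.14 ± 0.03) were higher, and CDKN1A (-0.04 ± 0.10) and RING1 (0.05 ± 0.03) did not pass. Of 15 PRC1 genes 2 were higher, PCGF2 (0.41 ± 0.07) among them, and 3 lower, CBX7 (-0.46 ± 0.10) and RYBP (-0.37 ± 0.04) among them. Of 11 PRC2 genes AEBP2 (0.28 ± 0.04) was higher and 4 lower, JARID2 (-0.59 ± 0.04) and EZH2 (-0.19 ± 0.03) among them. HOXB7 (2.52 ± 0.10), HOXB6 (1.52 ± 0.18) and HOXB9 (0.66 ± 0.14) were the 3 of 17 HOX genes that differed, all higher. Of 25 other developmental regulators 2 were higher, SOX9 (1.68 ± 0.15) most, and 7 lower, SOX2 (-2.05 ± 0.10) and OTX2 (-2.02 ± 0.16) most. BCL2A1 and OTX2 read 6.1 ± 3.28 and 7.7 ± 4.16 in the BMI1-shRNA line, near background, so the size of their differences depended on the pseudocount. The B cell genes MS4A1 (2.24 ± 0.10), BCL6 (1.26 ± 0.17), BACH2 (1.03 ± 0.17) and CD38 (0.97 ± 0.05) were higher, among 7 higher and 3 lower of 18 plasma cell and B lineage genes. Of 36 G2/M genes 11 were higher, UBE2C (2.98 ± 0.12) most, and 14 lower. None of these lists was called.

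The preset test called 2 lists. ATF4 genes were lower (3 higher, 15 lower and 11 not passed of 29, 5 and 15 adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.0466 with an estimated correlation). Serine and cysteine synthesis genes PHGDH (-1.37 ± 0.06), CTH (-0.85 ± 0.10) and PSAT1 (-0.75 ± 0.04) led it. Replication-dependent histones were lower (0 higher and 7 lower of 10, the same adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.15 with an estimated correlation), H2BC12 (-0.75 ± 0.04) most. Epithelial markers were not called (3 higher of 4, adjusted p = 0.0579): CDH1 (2.93 ± 0.08), KRT18 (0.51 ± 0.04) and EPCAM (0.20 ± 0.05) were higher. It was called after quantile normalization, tried after seeing the data, but not with an estimated correlation. The GAPDH 3-prime to 5-prime ratio was 0.935 against 1.03 in the control-shRNA line, and that of ACTB 1.16 against 1.18.

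In the comparison of 48 h with 0 h without doxycycline, which followed time in culture, cholesterol synthesis rose in both lines. In the control-shRNA line 13 of 18 measured genes of the pathway rose and none fell (16 adjusted over the list alone; adjusted p = 1.61e-31, and adjusted p = 6.75e-12 with an estimated correlation). HMGCS1, which makes hydroxymethylglutaryl-CoA, rose by 1.23 ± 0.12, the sterol sensor partner INSIG1 by 1.22 ± 0.07, MSMO1 by 1.07 ± 0.06 and LSS by 1.00 ± 0.07 (n = 3 a side). In the BMI1-shRNA line 9 of 18 rose and none fell (13 adjusted over the list alone; adjusted p = 6.98e-14, and adjusted p = 7.43e-08 with an estimated correlation), led by MSMO1 (0.58 ± 0.06), INSIG1 (0.57 ± 0.07), HSD17B7 (0.49 ± 0.08) and LSS (0.48 ± 0.07). The rises of 5 genes of the pathway, HMGCS1, INSIG1, MSMO1 and LSS among them, were smaller in the BMI1-shRNA line, in a test of the difference chosen after seeing the data. For INSIG1 the 48 h signals were close, 4349.5 ± 259 in the control-shRNA line and 4210.3 ± 275 in the BMI1-shRNA line. Its 0 h signals were 1871.5 ± 128 and 2829.9 ± 142 in that order. For MSMO1 the 0 h signals were close, 1664.0 ± 34.5 and 1607.9 ± 82, and the 48 h signals were 3501.2 ± 149 and 2400.3 ± 110. BMI1 had -0.12 ± 0.10 (limma adjusted p = 0.602) and -0.02 ± 0.10 (adjusted p = 0.944). The 0 h arrays of the BMI1-shRNA line are those with conflicting labels, and BMI1 read 1032 ± 32.4 on them.

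**Figure D4:**
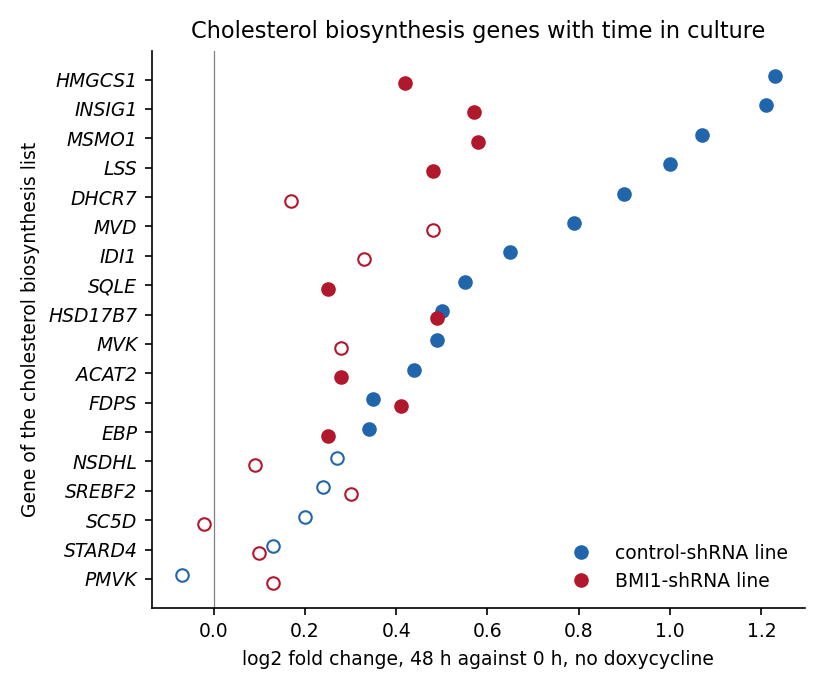
Log2 fold change from 0 to 48 h without doxycycline for the 18 measured cholesterol synthesis genes in each line, n = 3 arrays a side, with filled points where the limma adjusted p was under 0.05. In the control-shRNA line 13 points are filled and in the BMI1-shRNA line 9.

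Lists of the cell cycle were called in each line, without a test of their difference between lines. G2/M genes rose, 9 of 36 in the control-shRNA line (15 adjusted over the list alone; adjusted p = 9.57e-09, and adjusted p = 0.0024 with an estimated correlation) and 6 of 36 in the BMI1-shRNA line (11 adjusted over the list alone; adjusted p = 7.5e-05, and adjusted p = 0.0415 with an estimated correlation). CENPE rose by 0.37 ± 0.10 and 0.32 ± 0.10, and in both lines it lost the call without some single array and in another setting. G1/S genes fell, 7 of 37 with 1 up in the control-shRNA line (14 and 1 adjusted over the list alone; adjusted p = 2.62e-08, and adjusted p = 0.0109 with an estimated correlation) and 7 of 37 in the BMI1-shRNA line (11 adjusted over the list alone; adjusted p = 3.78e-07, and adjusted p = 0.026 with an estimated correlation). Cyclin E2, CCNE2, changed by -0.43 ± 0.10, a call lost in another setting, and by -0.68 ± 0.10. Mitochondrial ribosome genes fell, 3 of 29 and 1 of 29 (3 and 2 adjusted over the list alone), with adjusted p = 0.000119 and 0.0474, and adjusted p = 0.337 and 0.652 with an estimated correlation.

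Lists called in the control-shRNA line only were ATF4 genes (10 of 29 rose, 11 up and 2 down adjusted over the list alone; adjusted p = 4.03e-07, and adjusted p = 2.51e-05 with an estimated correlation), with CHAC1 (1.91 ± 0.43), CTH (0.99 ± 0.17), DDIT4 (0.96 ± 0.11) and SESN2 (0.86 ± 0.16), of which CHAC1 lost the call without some single array. Plasma cell genes were called there too (4 of 18 rose and 1 fell, 5 and 2 adjusted over the list alone; adjusted p = 0.0408, and adjusted p = 0.0541 with an estimated correlation), with TNFRSF17 (0.69 ± 0.06), POU2AF1 (0.67 ± 0.06) and IRF4 (0.43 ± 0.06). MYC targets were lower (4 of 25 fell, 5 adjusted over the list alone; adjusted p = 7.59e-05, and adjusted p = 0.265 with an estimated correlation). In the BMI1-shRNA line interferon-stimulated genes were called (4 of 26 rose, 5 up and 1 down adjusted over the list alone; adjusted p = 7.5e-05, and adjusted p = 0.00212 with an estimated correlation), OAS3 (1.77 ± 0.48) the highest, from a 0 h signal of 1.9 ± 2.17, under the pseudocount, and it lost the call without some single array and in another setting. Ribosomal proteins were higher there by a mean of 0.19 with 0 of 28 passing (adjusted p = 7.5e-05, and adjusted p = 0.655 with an estimated correlation; 0.00 after quantile normalization). The difference between the lines was not tested for these lists. Of called list members eligible for naming, 18 of 40 in the control-shRNA line lost the call without some single array and 22 in another setting, and 16 and 14 of 28 in the BMI1-shRNA line.

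In total 746 genes changed in the control-shRNA line (366 up, 380 down) and 656 in the BMI1-shRNA line (331 up, 325 down). Of the 746, 680 (91.2%) had the same direction in the other line and 234 passed in both. The complement gene C3 rose most in both, by 1.94 ± 0.37 and 2.54 ± 0.37, and ID1, an inhibitor of differentiation, fell in both, by 1.18 ± 0.16 and by 1.84 ± 0.16. The control-shRNA line also had rises of LOC105274304 (1.76), DNAJC5B (1.67), NRSN2 (1.67), OLMALINC (1.63), HCG27 (1.59), PRMT8 (1.57), MEIS3 (1.48) and CNTNAP3 (1.47). Its falls were ZNF396 (-1.71), FAS-AS1 (-1.64), TMEM229B (-1.48), LOC100507351 (-1.42), NOS1AP (-1.40), ITGB4 (-1.38), CSMD1 (-1.27), the chemokine CXCL9 (-1.19) and COL22A1 (-1.18). The BMI1-shRNA line had rises of CD4 (1.75), ST6GALNAC6 (1.73), LPAR2 (1.68), RAB38 (1.55), LOC105375875 (1.53), TRMT10B (1.52), MARCHF6-DT (1.48) and CYP3A5 (1.47). Its falls were PPP1R3B-DT (-1.43), ZMAT4 (-1.34), ZNF571-AS1 (-1.27), ID3 (-1.26), ADTRP (-0.99), BLZF1 (-0.96), STK11IP (-0.93), C1orf53 (-0.80) and CPEB4 (-0.79). These genes were taken from those whose groups do not overlap, which 10% of genes do by chance. Most are dim, and 27 of the 40 named lose the call without some single array.

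Of the genes always given, CDKN2B (0.95 ± 0.22), CDKN2A (0.29 ± 0.07) and IRF4 rose and CCND2 fell (-0.30 ± 0.08) in the control-shRNA line, and none passed in the BMI1-shRNA line. CDKN2A, CDKN2B and CCND2 lost the call in another setting, CDKN2B without replicate 2 of 48 h (0.77), and CCND2 without replicate 1 of 48 h (-0.26) or replicate 1 of 0 h (-0.29). Plasma cell genes PRDM1 (-0.48 ± 0.05) and SDC1 (-0.42 ± 0.12) fell in the BMI1-shRNA line, where both lost the call in another setting and SDC1 also without some single array, and the stress gene GADD45A fell in both (-0.73 ± 0.07 and -0.65 ± 0.07). The median array signal was 20.1 ± 2.56 at 48 h and 18 ± 0.833 at 0 h in the control-shRNA line, and 20.2 ± 2.29 and 17.5 ± 1.39 in the BMI1-shRNA line (n = 3 each). Without replicate 2 of 0 h the control-shRNA count was 492. The BMI1-shRNA count was 313 or 345 without replicate 1 or 2 of 48 h, and 298, 425 or 334 without replicate 1, 2 or 3 of 0 h.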

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

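Of the tests below, the counts of other splits of the arrays, the rank of the BMI1 line difference among all genes, the markers of other cell types, list tests after quantile normalization, and the differences between times and between the lines' time effects were chosen after the results were seen. Every result here is a tested difference between the lines or between times, except the surplus of falls at 24 h, whose balance was not tested.

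The doxycycline effects of the lines differed for 558 genes over the mean of 3 times, for 52 at 24 h, 138 at 32 h and 376 at 48 h. Doxycycline labels were exchanged between arrays within each line and time. For the mean, 1 of 100 splits, the real one, gave as many genes, the highest other giving 14. Chance in the spread between arrays can therefore be excluded. At 24 h 9 of 100 splits gave as many (highest other 64), at 32 h 5 of 100 (highest other 210) and at 48 h 9 of 100 (highest other 675), so these counts alone do not exclude chance at single times. The other 8, 4 and 8 splits all kept the real doxycycline groups of the BMI1-shRNA line, and so its effect, and relabelled the control-shRNA arrays only. No split drawn that broke up those groups gave as many. Of the 49 falls at 24 h, 47 were also falls at 48 h, on other arrays, where 1.05 would be shared by independent sets. Both times share one estimate of each gene's variance, so the sets are not fully independent. The BMI1 probe set differed by -2.47.

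The same test of the difference between lines singled out the genes named by rule on the mean of 3 times. The falls were IDH1 (-2.62), SFXN1 (-2.08), EVI5 (-1.81), ST6GALNAC6 (-1.42), ADA (-1.26), API5 (-1.19), MAPK6 (-1.18), LOC100507351 (-1.17), SLC39A10 (-1.17) and LGR6 (-1.16). The rises were LRRC17 (1.39), CCDC157 (1.38), ZNF771 (1.34), LINC00598 (1.23), SPINT1-AS1 (1.17), PSG4 (1.12), ANKRD36B (0.97), KDM4D (0.90), D2HGDH (0.82) and SOX2 (0.72). BCL2L11 (0.32) and RING1 (0.16) differed among the genes always given. ST6GALNAC6, LOC100507351, LGR6 and the 10 rises are dim next to IDH1, SFXN1, ADA, API5, MAPK6 and SLC39A10.

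Members of gene lists that differed were JARID2 (0.36), SUZ12 (-0.17), RBBP4 (-0.16), CDKN3 (-0.18), BNIP3L (-0.40), TP53INP1 (-1.13), FAS (-0.62), RRM2B (-0.36), PCNA (-0.40), DSCC1 (-0.32), KIF4A (-0.47) and AURKA (-0.36). CD38 (0.26), PDIA4 (-0.80), EDEM1 (-0.26), DNAJB9 (0.26), SLC7A11 (-0.78), MTHFD2 (-0.69), ATP5PB (-0.52), GFM1 (-0.27), MRPL37 (-0.26), MRPS30 (-0.20), LSS (-0.60), INSIG1 (0.20), ICAM1 (-0.26), JUN (-0.37) and UVRAG (-0.49) differed as well. Of 29 such members 16 lost the call in at least 1 other setting, and CD38, MRPS30, RBBP4 and SUZ12 without some single array. At single times SCML1 (0.64) and NETO2 (0.30) differed at 24 h, ADAD2-AS1 (3.00), TSPAN18 (2.79), CGREF1 (-2.36) and H3-4 (-2.31) at 32 h, and KIR3DL1 (2.33), LRP5L (1.80) and MED12L (-2.08) at 48 h. The list test called 4 lists at 24 h, 4 at 32 h and 1 at 48 h, against 0, 1 and 0 with an estimated correlation and none after quantile normalization.

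Between times, the knockdown effect at 48 h differed from that at 24 h for 2 genes, against 1092 at an unadjusted p under 0.05 in limma. SFXN1 went from -1.63 to -2.48 (difference -0.85 ± 0.15, adjusted p = 0.0163). STS, steroid sulfatase, went from 0.28 to 1.04 (0.76 ± 0.12, adjusted p = 0.00569). STS was chosen after its values were seen. The change from 0 to 48 h without doxycycline differed between the lines for 21 genes, 9 up and 12 down, against 1123 at an unadjusted p under 0.05.

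Falls outnumbered rises among genes that responded to the BMI1 hairpin at 24 h beyond the control line, 49 of 52 (94.2%). Array scaling was argued against, since 96.5% fell after quantile normalization, and so was noise at dim probe sets, since 95.2% fell with a filter at the 75th percentile. Silencing of other transcripts by the hairpin itself stays open. Genes that fell at 32 h had reached a median 0.564 of their 48 h change at 24 h (quartiles 0.409 and 0.72, 110 genes), between the bounds set for a direct and a delayed effect, against 0.445 for 28 rises and 0.83 for BMI1. With 1 hairpin against BMI1, IDH1, SFXN1 or ADA could be lowered by loss of BMI1 or by the hairpin, and the design cannot separate these. Each hairpin was carried by a single line, so a response to doxycycline particular to that line is not separated either.

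BMI1 was lower without doxycycline in the BMI1-shRNA line, at 80% of the control-shRNA level. Expression of the hairpin without doxycycline was tested on other genes, and only a leak strong enough to move them was argued against. The 381 genes that fell more in that line had a median line difference at 0 h of -0.007. This was at percentile 73.3 of expression-matched random lists, where a leak predicted values under percentile 2.5. The 177 genes that rose had a median of -0.044, at percentile 2.84. A broad difference between the lines could also give the BMI1 value, since 69.6% of genes had a smaller line difference. That percentage does not exclude a leak. The leak test rests on the 0 h arrays of the BMI1-shRNA line, whose labels conflict. All arrays of that line lay apart from the control-shRNA line on the first principal component. BMI1 read 1032 ± 32.4 on these 0 h arrays, against at most 234 on dosed arrays. These values argue against arrays of the control-shRNA line and against an induced hairpin. BMI1 itself differed by only -0.32 between the lines without doxycycline, against -2.43 on induction in the BMI1-shRNA line (log2, means of 3 times). A leak of that size predicts only a small shift in the other genes, which the test may not resolve. A leak too weak to move the other genes stays open.

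Without doxycycline 6443 genes differed between the lines, and 1 of 100 splits, the real one, gave as many, the highest other giving 2946. Chance in the spread between arrays can therefore be excluded. Each hairpin was carried by a single line and the replicates may not be separate cultures. The splits thus cannot exclude chance differences between cultures. Exchanging lines for some arrays only leaves part of the difference between lines in place, a structure of the arrays. Cells of another type stay open: the largest mean difference of a marker list was 0.867, for epithelial genes (CDH1 at 378 against 45.5, EPCAM at 3440.8 against 2987.6), and the bound of the test was set after the values were seen. A line in which MAF or ITGB7 is low was argued against, since both, high in RPMI-8226, were at percentile 98.9 or above on every array. These genes alone cannot tell RPMI-8226 from another line in which both are high. Differences in gene copy number may contribute: neighbouring genes correlated at 0.182 across genes, above the 0.023 of the highest of 1000 shuffles, and 23 of 25 neighbours from RAD52 to NDUFA9 on chromosome 12 were higher.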

How the results depend on the processing

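Means of 24 and 32 h, fits without the 0 h arrays and list tests after quantile normalization were chosen after seeing the data. The BMI1 probe set kept its direction and its side of the threshold in 355 of 355 values, and its difference between lines ran from -2.51 to -2.35 over 49 settings. Of 10129 values of named genes in the other settings set beforehand, 9656 kept direction and call, 415 lost the call, 52 gained it and 6 reversed. Of 14178 values with an array left out, 13303 kept both, 805 lost the call, 70 gained it and 0 reversed.

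Counts of changed genes stayed within 1.5 times in every comparison with pseudocounts of 1 and of the median value, no filter, the 75th percentile filter, no intensity trend, the replicate block and without the 0 h arrays. Quantile normalization moved only the control-shRNA line at 48 h, to 11; the cause was not tested. The mean of a gene's probe sets gave 207 in the BMI1-shRNA line at 32 h, 3 and 1 in the control-shRNA line at 24 and 32 h, and 32 for the difference at 24 h. It reversed PRDM1 (-0.0236, doxycycline in the control-shRNA line), CCND2 (-0.245) and GINS2 (0.122) for time in the BMI1-shRNA line, COL1A1 (0.645) for time in the control-shRNA line, and SUZ12 (0.198 in the BMI1-shRNA line, 0.337 for the difference). It averages probe sets that can read different transcripts, and the cause was not tested.

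All probe sets as features, which tests more items, gave 2054, 486 and 1348 in the BMI1-shRNA line (mean, 32 h, 48 h), 3 and 4 in the control-shRNA line at 32 and 48 h, 893 and 583 for the difference (mean, 48 h), 12362 between lines and 1253 for time in the control-shRNA line. Fitting only the groups of the comparison, with fewer residual degrees of freedom, gave 140, 146 and 414 in the BMI1-shRNA line and 3, 1 and 1 in the control-shRNA line at the 3 times, 75 and 159 for the difference at 32 and 48 h, and 226 and 333 for time in the control-shRNA and BMI1-shRNA lines. The mean of 24 and 32 h, with fewer arrays, gave 575, 12 and 207 for the BMI1-shRNA line, the control-shRNA line and the difference.

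With an estimated correlation 0, 1 and 0 lists were called for the difference at 24, 32 and 48 h, 1 between lines and 4 for time in the control-shRNA line; the cause was not tested. Quantile normalization in the list test left 0, 0 and 0 for the difference, and the replicate block in the list test called 1 list for doxycycline in the control-shRNA line, plasma cell genes.

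Leaving out 1 array at a time gave 1071 to 1196, 138 to 164, 214 to 327 and 616 to 676 genes in the BMI1-shRNA line (mean, 24, 32, 48 h), 16 to 21, 3 to 6, 2 to 7 and 4 to 7 in the control-shRNA line, and 494 to 596, 41 to 50, 103 to 148 and 294 to 366 for the difference. It gave 6198 to 6330 between lines and 492 to 786 and 298 to 490 for time in the control-shRNA and BMI1-shRNA lines. With 3 arrays a group, signals near background limit what can be called: on simulated data 65% of changes of log2 0.5 were recovered over 3 times.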

Other observations

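The splits of arrays, the test of a doxycycline effect common to both lines, the difference of the lines' time effects and the relations within groups were chosen after the results were seen; the test of neighbouring genes was set before.

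For doxycycline over 3 times in the BMI1-shRNA line (1220 genes), 1 of 100 splits, the real one, gave as many, the highest other giving 303. Chance in the spread between arrays can therefore be excluded. In the control-shRNA line (19 genes), 2 of 100 splits gave as many. This share under 0.05 argues against chance in the spread between arrays without excluding it. The other split called 210, several times the real count, which points to a structure of the arrays. Its sides differed in median array signal by 1.94, against 0.0111 for the real split. Whether this gave the 210 calls was not tested. Single comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many. For the BMI1-shRNA line the real counts were 237, 322 and 789 and the highest others 1, 3 and 9 at 24, 32 and 48 h. For the control-shRNA line they were 6, 7 and 7 with highest others of 0, 1 and 2. For 48 h against 0 h they were 746 and 656 with highest others of 1 and 2 in the control-shRNA and BMI1-shRNA lines.

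Of the 19 genes that changed with doxycycline in the control-shRNA line, 16 (84.2%) had the same direction in the BMI1-shRNA line, measured on separate arrays, and 11 passed in both, SLITRK5 and SLC18B1 (-0.79 and -0.52) among them. An effect of doxycycline itself, or of inducing any hairpin, is consistent with these genes. Across 14705 genes, which are not independent replicates, the doxycycline effects of the lines correlated at r = -0.001.

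BMI1 acts on chromatin, so neighbouring genes might be released together when it is lost. Across genes the difference of doxycycline effects correlated between neighbours at 0.013, within the range of 1000 shuffles of gene order (highest 0.026). This argues against such blocks over much of the genome. The value is taken over 14633 pairs of neighbours, most of whose genes did not change, so blocks at a few loci stay open.

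The 21 genes whose change from 0 to 48 h differed between the lines held 5 of cholesterol synthesis. Genes given here that the naming rule does not name were chosen after their values were seen. The 5 were HMGCS1 (-0.81), DHCR7 (-0.73), INSIG1 (-0.64), LSS (-0.52) and MSMO1 (-0.49), which rose less in the BMI1-shRNA line. The interferon-induced chemokines CXCL9 (1.03) and CXCL10 (0.91) and lymphotoxin LTB (0.97) fell from 0 to 48 h in the control-shRNA line, by 1.19, 0.75 and 0.73 on the log2 scale, and changed by -0.16, 0.16 and 0.24 in the BMI1-shRNA line. TNFRSF17 (-0.64) and IRF4 (-0.39), genes of plasma cells, rose by 0.69 and 0.43 in the control-shRNA line and had 0.04 each in the other, neither passing. The anti-inflammatory ANXA1 (-1.01) and the glucocorticoid-induced TSC22D3 (-0.95) also differed. The 0 h arrays of the BMI1-shRNA line carry conflicting labels. On the first principal component all arrays of that line sat at 27.403 or above, and those of the control-shRNA line at -27.255 or below. BMI1 read 1009.3 to 1069.4 on these 0 h arrays, against at most 234 on dosed arrays of that line. These values argue against arrays of the control-shRNA line and against an induced hairpin at 0 h.

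Within groups, 4 relations were computed over the 42 arrays after removing group means. The median signal of an array went with the first component of the remaining spread (8.63% of it; r = 0.940, rho = 0.948, permutation p = 1e-05 for each, the smallest that 100000 permutations can give, and 1e-05 after adjustment). The percent of signal in the 100 brightest probe sets went with the second component (4.95%; r = 0.808, rho = 0.752), with the mean of the ribosomal protein list (r = 0.987, rho = 0.990) and with that of oxidative phosphorylation (r = 0.877, rho = 0.872), each at the same permutation p. Without the 2 arrays farthest from the median of the x axis, r was 0.938, 0.751, 0.984 and 0.834 in that order. Of the 28 ribosomal probe sets 11 are themselves among the 100 brightest, and both components are computed from the same signals as the measures set against them. These relations are therefore partly fixed by construction, and their p-values are not evidence of a separate cause.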
